A study of Mus musculus with 12 samples.

How the data were processed

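RNA was sequenced from kidney cortex of C57BL/6J mice in 12 libraries, 3 in each of 4 groups. NASH, non-alcoholic steatohepatitis, is a fatty and inflamed state of the liver. Per the labels' protocols, NASH mice had a Western diet with carbon tetrachloride (CCl4), a liver toxin, and control mice a normal diet with corn oil, for 12 or 24 weeks. The labels give 6 mice for each group at 12 weeks, 8 for the controls at 24 weeks and 10 for the NASH group at 24 weeks, with as many males as females in every group, and RNA integrity above 7.5. They do not give the sex behind a library or the hour of dissection. Nothing in them says whether libraries came from separate animals or from pools, so every p below measures the spread between these samples.

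Per the submitters' processing notes, the authors used BWA, limma and mouse build mm10; versions and the role of each tool are not given. The deposited values are log2 values, normalized per the file headers, for 11614 genes in each library, with RefSeq gene models. Their steps were tested on the values, with 1 step per library. Of the values below 60 steps, 85.4% to 91.1% were whole multiples of the step, within 0.01 steps. Between 98.2% and 100% were whole multiples or the geometric mean of 2 of them. The deposited log2 values are therefore read counts times 1 factor per library on the log2 scale, and genes with an even number of transcripts often hold a mean over 2 transcripts. How the authors set the factor is not stated. It ranged from 1.00 to 1.96, and the scaled totals from 13600000 to 14100000 reads. Every gene reaches 100 scaled reads (log2 6.64) in at least 1 library, so genes had been filtered before deposition by a rule that is not stated, and a gene missing from the files is not shown to be unexpressed. A spreadsheet-like change had turned 16 symbols into dates, and 9 genes had no gene ID. No gene ID was held by 2 genes. Coordinates are those of the files on mm10; starts were raised by 1, because the length equalled end minus start in 234 genes and end minus start plus 1 in 0.

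The deposited log2 values were used as they are. Each gene was fitted with limma 3.58.1 in R 4.3.3 by a model of 4 group means over all 12 libraries, and 2-sided moderated tests with a mean-variance trend were adjusted by Benjamini-Hochberg over 11614 genes; a gene is called at an adjusted p under 0.05. A filter on a mean log2 value of at least 1 removed 0 genes. The contrasts are NASH against control at 12 weeks and at 24 weeks, the difference of these effects (24 minus 12 weeks), 24 against 12 weeks in control and in NASH mice, and the NASH effect averaged over both times. Called genes shared by both times were counted with Fisher's exact test. Changes are log2 differences with their standard error (SE); groups are given as mean ± SD. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

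The contrasts, the tests, 38 gene lists, the rule for named genes and a first set of alternatives were chosen before the data were examined. Of 728 listed genes 604 were measured. Lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the 34 lists with at least 5 measured genes; the alternatives were an estimated correlation and fry. Neutrophil (0 of 12) and adrenal cortex (0 of 9) markers had no measured gene, and T and NK cell (1 of 17) and B and plasma cell (1 of 13) markers had 1 each. Within a list, members were also adjusted over the list alone. The rule names, at each time, up to 12 genes per direction with the largest change among those called, above the median level (log2 8.62) in the higher group and with no overlap between the 3 NASH and 3 control libraries. For the other contrasts it names up to 5 per direction. Where fewer than 5 pass, it takes the 5 with the smallest p and says that they do not pass. It was applied with and without the replicate block. For the difference and the average the overlap of libraries was not asked. Up to 12 per direction were named for the average effect, which was decided after the data were seen. Predicted loci are not named, and some genes that the rule names are not reported here. Col1a1, Fn1, Acta2, Havcr1, Lcn2, Plin2, Cpt1a, Slc34a1 and Xist are always given, and the 2 to 4 members with the smallest p for each list described.

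Replicates 1, 2 and 3 occur in every group. Whether to fit these numbers as a block was decided from the correlation of deviations from the group means, before the calls of the fits were compared. All 18 same-numbered pairs correlated above 0.1, from 0.19 to 0.74, and the block was fitted on that ground. Pairs of replicates 2 with 3 also all lay above 0.1, from 0.19 to 0.64. The correlations therefore show replicate 1 apart from the others, and do not settle whether 2 and 3 pair by number. The labels do not say what a number stands for. The median was 0.70 for replicate 1 with 1, 0.40 for 2 with 2 and 0.43 for 3 with 3, against 0.36 for 2 with 3, -0.50 for 1 with 2 and -0.56 for 1 with 3. Of 12 libraries 9 correlated best with a library of their own number. A fit with the replicate number as a block is therefore given beside a result wherever it changes a call or moves a count more than 1.5 times. Replicate 1 of each group had high Xist, the X-inactivation RNA of female cells, and replicates 2 and 3 had low Xist. High-Xist libraries are 1 per group and allow no test of their own, so values within this split come from replicates 2 and 3.

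Other alternatives were pseudocounts, filters, quantile normalization, median-of-ratios scaling, no trend, sample quality weights, Xist level as a covariate, the compared groups alone, and each library left out in turn. After the data were seen, these were added: replicates 2 and 3 alone; the block combined with each scaling, with a mean of at least 100 scaled reads, with each library left out, or with a trend on GC content and length removed; that filter without the block; and covariates for Xist and a clock index, the mean level of Dbp, Tef, Hlf, Per1, Per2, Per3, Nr1d1 and Nr1d2 minus that of Arntl, Clock, Npas2 and Nfil3. GC content was known for 11579 genes (99.7%). Count models were not run, since whole reads could be recovered only in part.

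The 12-week test was tested on simulated data for 11614 genes, of which 11414 did not change. It recovered 88.0% of 50 genes at a log2 change of -2, 44.0% at -1, 48.0% at 1 and 82.0% at 2, and called 0 unchanged genes. With the block it recovered 100% at -2, 66.0% at -1, 74.0% at 1 and 96.0% at 2, and called 10 unchanged genes. The simulated data used the replicate effects and residual spread of the block fit, with independent noise for each gene. The gain with the block is therefore built in, and shifts shared by many genes were not simulated.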

Results

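The data are RNA sequencing profiles of mouse kidney cortex from 4 groups of 3 libraries: control and NASH mice at 12 weeks and at 24 weeks. Per the labels, NASH mice differ from controls in diet, CCl4 and liver disease at once. No contrast can part these, so a NASH effect here means them together. Estimated from the steps of the values, depth ranged from 7170000 reads in NASH at 12 weeks, replicate 2, to 14100000 in control at 24 weeks, replicate 2. At 12 weeks it was 12700000, 13700000 and 13100000 reads in the controls and 12400000, 7170000 and 8230000 in NASH. At 24 weeks it was 10100000, 14100000 and 11200000 in the controls and 12300000, 11300000 and 8280000 in NASH. Gpx3 was the most abundant gene in every library but NASH at 12 weeks, replicate 3, where Kap was, and the top gene held 3.3% to 5.2% of the scaled total. The squared difference between replicates exceeded sampling variance by medians of 1.99 to 13.4 times, so no replicates were copies of 1 library.

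The replicate numbers separated the libraries more than the groups did. Xist was at log2 10.6 to 11.5 in replicate 1 of all 4 groups and at 2.97 to 4.86 in replicates 2 and 3. Ddx3y ran the other way, at 2.48 to 4.25 in replicate 1 and 8.95 to 9.62 in replicates 2 and 3. Kap, an androgen-regulated protein of the mouse proximal tubule, was at 12.4 to 16.9 in replicate 1 and 18.2 to 19.2 in the others, and the organic anion transporter Slco1a1 at 3.74 to 5.25 against 11.3 to 13.4. The first principal component, which parts replicate 1 from the others, held 49.7% of the variance. Xist did not differ between NASH and control (log2 change -0.61, SE 2.85, at 12 weeks and 0.12, SE 2.85, at 24 weeks), and the sex chromosome list did not pass at either time (medians -0.38 and 0.015, camera adjusted p = 0.894 and 0.849). At 12 weeks its test pointed up against a median and mean below 0, and at 24 weeks its mean and test lay below 0.

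**Figure D1:**
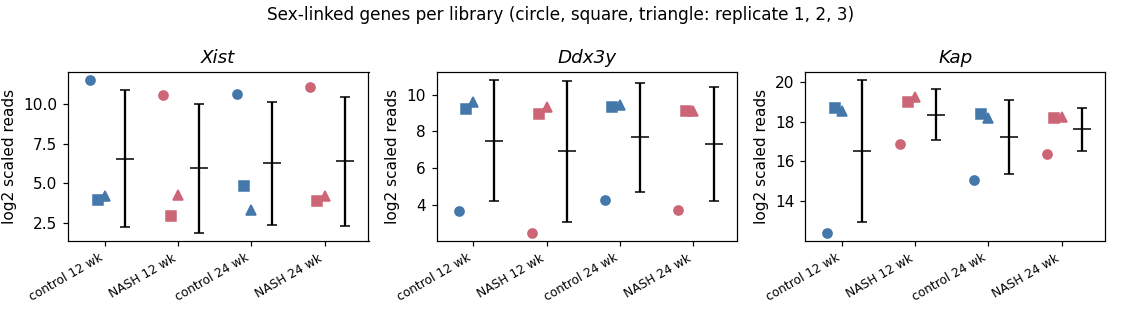
Log2 scaled reads of Xist, Ddx3y and Kap in each of the 12 libraries (points; circle, square and triangle are replicates 1, 2 and 3), by group, with the group mean ± SD of 3 libraries as bars. Replicate 1 has Xist at 10.6 to 11.5 in every group, and replicates 2 and 3 have it at 2.97 to 4.86.

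At 12 weeks, 2 genes of the circadian clock differed most among the genes called without the block. Dbp, a transcription factor that carries the clock's output, was 44.7-fold higher in NASH (log2 change 5.48, SE 0.78, n = 3 per group), and Npas2, which pairs with the clock's activator Arntl, was 6.10-fold lower (-2.61, SE 0.28). Slc16a1, a transporter of lactate and other monocarboxylates, was 3.76-fold lower (-1.91, SE 0.20), and Ndrg1, a gene induced by low oxygen, 2.69-fold lower (-1.43, SE 0.19). Coq10b, which binds coenzyme Q, was 2.28-fold higher (1.19, SE 0.17).

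Of 11614 genes limma called 6, 2 higher and 4 lower, with adjusted p of 0.0468 for Dbp and Coq10b, 0.00984 for Slc16a1 and Npas2, and 0.0339 for Ndrg1. All 3 same-numbered pairs moved the same way for each of Dbp, Coq10b, Slc16a1, Npas2 and Ndrg1. Within replicates 2 and 3 the changes were 5.79 for Dbp, 1.43 for Coq10b, -2.03 for Slc16a1, -2.99 for Npas2 and -1.52 for Ndrg1. On mm10, Dbp (gene ID 13170) lies on chromosome 7 from 45705247 to 45710203 and Coq10b (67876) on chromosome 1 from 55052770 to 55072702. Slc16a1 (20501) lies on chromosome 3 from 104638664 to 104658462, Npas2 (18143) on chromosome 1 from 39194272 to 39363240, and Ndrg1 (17988) on chromosome 15 from 66929318 to 66969641. Next by p, and not passing, were Nr1d2 (1.33), Sorbs3 (0.79) and Prss8 (0.63) on the higher side and Gsta3 (-1.26) on the lower side, with adjusted p from 0.0849 to 0.166. The fit without a block gave 0 genes without replicate 2 or 3 of either 12-week group, 2 without control 24-week replicate 2 or 3 or NASH 24-week replicate 3, 3 without control 12-week replicate 1 or NASH 24-week replicate 2, and 11 without NASH 12-week replicate 1, where Dbp was not called (adjusted p = 0.078). Without control 12-week replicate 1 Dbp and Ndrg1 (0.13 for both) and Coq10b (0.051) were not called. The fit of the 6 compared libraries alone called 1, and quantile normalization, median-of-ratios scaling and no trend each ended the calls of Dbp (adjusted p = 0.077, 0.069 and 0.077) and Coq10b (0.077, 0.086 and 0.088). Median-of-ratios scaling also ended that of Ndrg1 (0.13).

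With the replicate block 1494 genes were called at 12 weeks, 350 higher and 1144 lower, against 3580 at an unadjusted p under 0.05. Beyond the clock genes, those higher by the naming rule were led by Ttr, a thyroid hormone and retinol carrier (6.80-fold, log2 2.77, block SE 0.59, adjusted p = 0.0185), and held the lipid transporter Mfsd2a (2.63), the carriers Slc38a3 (2.21), Slc5a10 (2.09) and Slc13a2 (1.43), Pck1, the entry enzyme of gluconeogenesis (3.68-fold, 1.88, block SE 0.48), Napsa (1.74) and the water channel Aqp2 (1.46). Those lower included Ppard, a nuclear receptor for fatty acids (3.99-fold lower, -1.99, block SE 0.38), Ypel2 (-1.77), Lonrf3 (-1.62), Dtx4 (-1.56), A1cf (-1.36), C1galt1 (-1.35), Rhobtb1 (-1.34) and Chic1 (-1.34). Replicates 2 and 3 alone gave 385 calls (95 higher, 290 lower), with Ttr at 2.57, Pck1 at 2.25 and Ppard at -2.59, and Xist as a covariate gave 753 (163 higher, 590 lower). The split by direction moved with scaling: the block gave 686 higher and 693 lower under median-of-ratios scaling and 532 higher and 698 lower under quantile normalization, and the median change of all genes was -0.080, 0.0074 and -0.0045 as deposited and under these scalings. The block's count fell to 253 without control 12-week replicate 3, 326 without NASH 12-week replicate 1, 410 without control 12-week replicate 2, 596 without NASH 12-week replicate 2 and 679 without control 12-week replicate 1, and to 519 (90 higher, 429 lower) after the GC and length trend was removed. That trend's removal also ended the calls of Napsa (then 1.52, adjusted p = 0.11), Slc38a3 (2.11, 0.063), Pck1 (1.82, 0.063), Aqp2 (1.11, 0.11) and Nr1d1 (1.09, 0.062), whose changes were 1.74, 2.21, 1.88, 1.46 and 1.19 before. Leaving out single 12-week libraries ended those of Napsa, Slc38a3, Pck1, Aqp2, Nr1d1, Ttr, Mfsd2a, Slc5a10, Ppard and Lonrf3, with adjusted p up to 0.16, and leaving out 24-week libraries that of Napsa (up to 0.070), as did quantile normalization (0.059).

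Of the 16 measured clock genes, 9 were higher and 4 lower adjusted over the list alone, against 1 higher and 1 lower over all genes. With the block 8 rose and 4 fell over all genes. Dbp, Per3 (1.69, block adjusted p = 0.00276), Nr1d2 (1.33) and Nr1d1 (1.19) were on the higher side, and Npas2 and Arntl (-1.64, block SE 0.21) on the lower. The list's median was 0.51 with a camera adjusted p of 0.0139, and an adjusted p = 0.347 with an estimated correlation. The call was lost under quantile normalization (0.15), median-of-ratios scaling (0.11) and without control 12-week replicate 2 (0.087). With the block it was lost under these scalings (0.20 and 0.19), without control 12-week replicates 2 (0.19) or 3 (0.061) and without NASH 12-week replicate 2 (0.082). Per3 was at log2 6.49 ± 0.25 in control and 8.18 ± 0.31 in NASH (SD, n = 3).

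**Figure D2:**
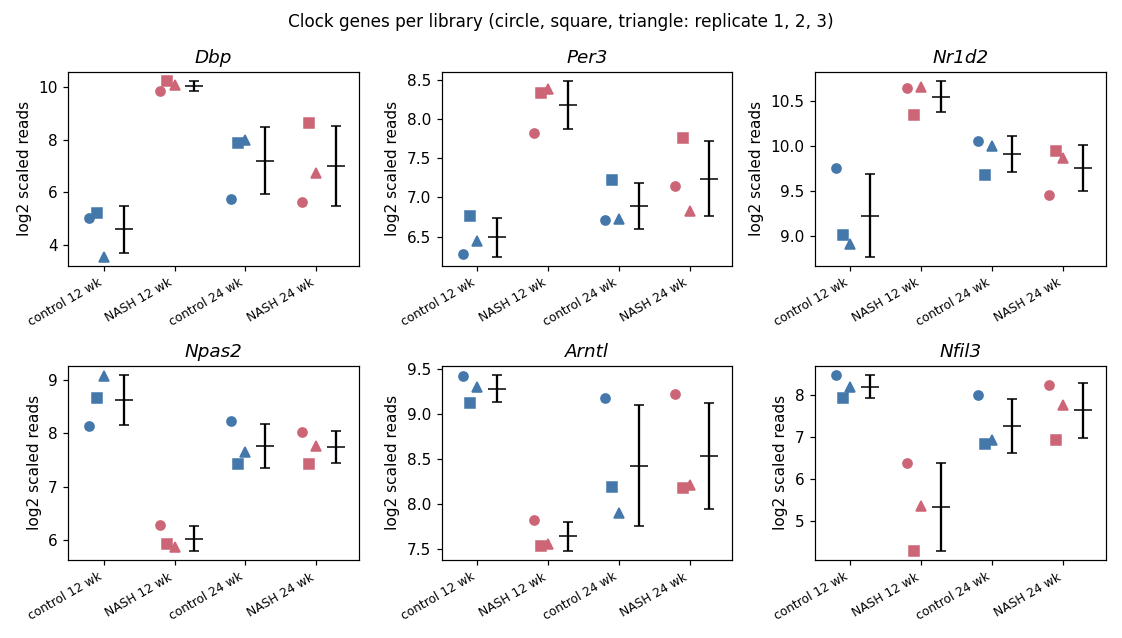
Log2 scaled reads of 6 clock genes in each of the 12 libraries (points; circle, square and triangle are replicates 1, 2 and 3), by group, with the group mean ± SD of 3 libraries as bars. Dbp lies at 9.87 to 10.2 in the NASH libraries at 12 weeks and at 3.54 to 5.19 in the controls of that time, while the 24-week groups overlap.

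Genes of mitochondrial oxidative phosphorylation were higher as a group at 12 weeks: 39 of 43 had a positive change, with a median of 0.31 (camera adjusted p = 4.4e-17; adjusted p = 0.720 with an estimated correlation). Adjusted over the list alone 12 were higher and 0 lower, and 28 with the block. Over all genes the block called 13 higher. Cox7c (0.62), Uqcrq (0.89), Cox6a1 (0.64) and Ndufb8 (0.57), subunits of the respiratory chain, had the smallest p. After the GC and length trend was removed the list's median was 0.0073 with the block, with a camera adjusted p of 0.0183. The changes of Cox7c, Cox6a1 and Ndufb8 were then 0.25, 0.13 and 0.15, and they were not called (adjusted p = 0.12, 0.46 and 0.53). Uqcrq was not called with the block without NASH replicate 1 (adjusted p = 0.059). The tricarboxylic acid cycle list passed at a median of 0.091 (0.0358; adjusted p = 0.720 with an estimated correlation), with Sdhb at 0.29 and Idh3g at 0.25, and lost its call under quantile normalization (0.73) and without replicates 2 or 3 of the controls (0.15, 0.10) or NASH replicate 2 (0.12). With the block it was lost under quantile normalization (0.88), without replicates 2 or 3 of the controls (0.27, 0.077) and without NASH replicates 2 (0.15) or 3 (median 0.023, adjusted p = 0.070). The gluconeogenesis and glycolysis list passed at a median of 0.19 (0.0139; adjusted p = 0.720 with an estimated correlation). Its members went both ways: with the block Pck1 rose and G6pc, which releases glucose from glucose 6-phosphate, fell (-0.80, adjusted p = 0.0434). G6pc was lost under median-of-ratios scaling (0.082), with the GC and length trend removed (change -0.81, adjusted p = 0.075) and without any of 8 libraries (0.051 to 0.16). With the block and that trend removed the medians of the tricarboxylic acid cycle (0.038, adjusted p = 0.0835) and gluconeogenesis (0.14, adjusted p = 0.0756) did not pass. The gluconeogenesis call was lost under quantile normalization (0.15) and without control replicates 2 or 3 (0.087, 0.070) or NASH replicate 1 (0.055), and with the block under quantile normalization (0.20) and without control replicate 3 (0.059).

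Interferon-response genes were also higher, 25 of 27 with a positive change and a median of 0.45 (camera adjusted p = 6.1e-04; adjusted p = 0.763 with an estimated correlation). Irf7, a driver of the interferon response, rose with the block (1.18, 2.26-fold, adjusted p = 0.0268), and Ifit3 was at 1.25 (0.0638). Irf7 was lost with the GC and length trend removed (change 0.99, adjusted p = 0.067), without control replicates 1 (0.089) or 3 (0.11) and without NASH replicates 1 (0.10) or 3 (0.077). The list's call was lost without control 12-week replicate 3 (0.063), as with the block (median 0.19, adjusted p = 0.061). Of 17 genes of the unfolded protein response 13 were positive, with a median of 0.23 (0.00752; adjusted p = 0.720 with an estimated correlation). Asns, asparagine synthetase, rose with the block (1.03, adjusted p = 0.0399), while Xbp1 (0.46), Ddit3 (0.68) and Atf4 (-0.31) did not pass. Asns was lost with the GC and length trend removed (change 0.97, adjusted p = 0.085) and without each 12-week library (0.059 to 0.14). The list's call was lost without control replicates 2 (0.087) or 3 (0.070), and with the block without these (0.13 and 0.064) or under quantile normalization (0.13).

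Markers of cells outside the nephron moved in the same comparison. Adipocyte markers passed as a list at a median of 1.08 (0.0190; adjusted p = 0.730 with an estimated correlation), erythroid genes at 0.80 (0.0139; adjusted p = 0.730 with an estimated correlation) and hepatocyte markers at 0.62 (0.0389; adjusted p = 0.720 with an estimated correlation), the last not with the block (0.079) while Ttr and Apoa2 (1.12, adjusted p = 0.0377) rose with it. No adipocyte or erythroid gene passed singly. Adipoq was at 2.02 and Hba-a1 at 1.22. Apoa2 was lost with the GC and length trend removed (change 0.64, adjusted p = 0.20) and without control 24-week replicate 3 (0.052) or each 12-week library (0.064 to 0.11). The adipocyte median was 0.70 (adjusted p = 0.0287) and the erythroid median 0.52 (0.0386) with the block and that trend removed. Hbb-bt and Hbb-b2 hold identical values. The erythroid call was absent within replicates 2 and 3 (median 0.32, adjusted p = 0.219), and the adipocyte and hepatocyte calls were lost under quantile normalization (0.15 for both), median-of-ratios scaling (0.091 and 0.12) and without control replicates 2 (0.14 and 0.19) or 3 (0.081 for both) or NASH replicate 1 (0.10 and 0.13). They were also lost with a mean log2 value of at least 5 (0.083 and 0.095) or of log2 of 100 (0.27 and 0.51), where the hepatocyte median was -0.0066, and the hepatocyte call without NASH replicate 3 (0.058). Without control replicate 2 the erythroid call was lost too (0.087), as it was without NASH replicate 1 (0.20). The block's erythroid call was lost without replicate 1 of control (median 0.40, adjusted p = 0.092) or NASH (0.075) and under median-of-ratios scaling (0.067) and quantile normalization (0.070). Its adipocyte call was lost without control replicates 2 (median 0.71, adjusted p = 0.19) or 3 (0.063), without NASH replicate 2 (0.070) and under these scalings (0.16 and 0.20). Lipid droplet and uptake genes passed with the block alone (median 0.29, 0.0400; without it 0.0754; adjusted p = 0.640 with the block and an estimated correlation), and not with it under median-of-ratios scaling (0.11) or quantile normalization (0.20), without control replicates 1 or 3 (0.064 for both) or without NASH replicates 1 (0.062) or 2 (0.066).

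The other lists did not pass at 12 weeks. Fibrosis genes (extracellular matrix and fibroblast activation) had a median of 0.018 (camera adjusted p = 0.394), with Col1a1 at 0.32 (SE 0.39), Fn1 at 0.34 (SE 0.66), Acta2 at 0.47 (SE 0.43) and Vim at 0.65. Tubular injury genes had 0.23 (0.394), with Havcr1, the kidney injury molecule, at 0.37 (SE 0.97) and Cdkn1a at -1.24. Lcn2 was not among the deposited genes. Lipid lists lay near 0 or below: fatty acid synthesis -0.026 (0.474; its mean and test were above 0), cholesterol synthesis -0.22 (0.515) and fatty acid oxidation 0.019 (0.439), with Plin2 at 0.29 (SE 0.45) and Cpt1a at -0.22 (SE 0.24). With the block Gpam fell (-0.94), Dgat2 rose (0.46), and in cholesterol synthesis Fdps (-0.71) fell and Ebp (0.67) rose. NRF2 targets had 0.075 (0.391), cytokines 0.10 (0.124), complement 0.095 (0.419) and macrophage markers 0.19 (0.124). The 1 measured T and NK cell marker, Cd8b1, was at -0.32 at 12 weeks and -0.80 at 24 weeks, and the 1 B and plasma cell marker, Xbp1, at 0.46 and -0.15. Immediate early genes had 0.15 (0.0942), with Junb (1.22) and Ier2 (1.36) higher with the block.

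Nephron and vessel markers gave medians of -0.089 for proximal tubule (0.439, test pointing up), with Slc34a1 at -0.10 (SE 0.18), -0.26 for podocytes (0.657), -0.22 for the loop of Henle and distal tubule (0.730), -0.17 for collecting duct (0.394, mean and test above 0), 0.0043 for endothelium (0.634, mean below 0) and -0.023 for the juxtaglomerular list (0.646, mean and test above 0). Male-biased kidney genes had 0.24 (0.419), female-biased 0.28 (0.391), cell cycle -0.18 (0.691), cytochrome P450 genes -0.044 (0.639, mean and test above 0), retinoid genes -0.20 (0.509), bile acid handling 0.25 (0.394) and amino acid metabolism -0.16 (0.893). With the block 5 of 16 loop and distal tubule genes fell, among them Slc8a1 (-1.62), Calb1 (-1.15), Trpv5 (-0.89) and Slc12a3 (-0.66), which serve calcium and salt transport there. Slc51a, a subunit of the basolateral bile acid exporter, rose with the block (1.13, adjusted p = 0.00859) and Rdh10, a retinol dehydrogenase, fell (-0.98, 0.00394).

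**Figure D3:**
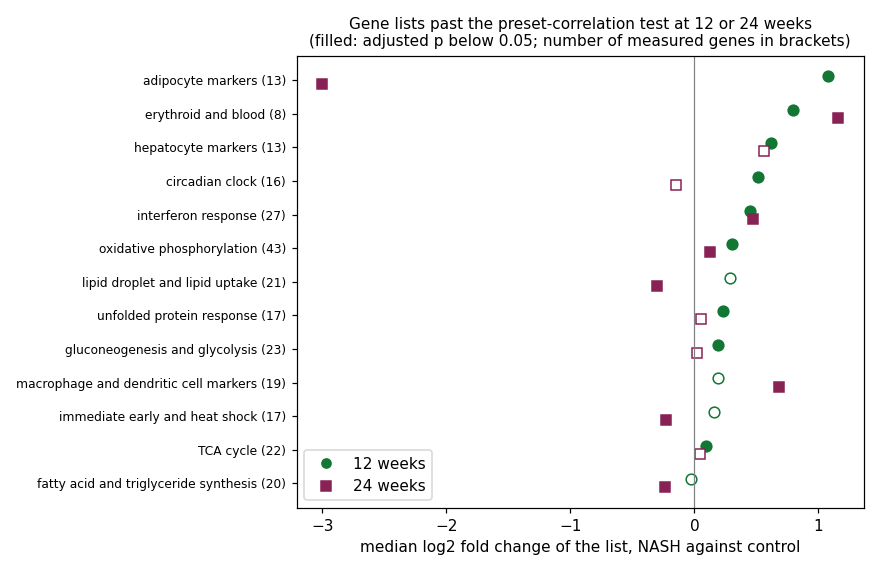
Median log2 change between NASH and control of each gene list (y axis, number of measured genes in brackets) at 12 weeks (circles) and 24 weeks (squares); filled symbols have a camera adjusted p under 0.05 at a preset correlation of 0.01. Adipocyte markers have a median of 1.08 at 12 weeks and -3.00 at 24 weeks.

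At 24 weeks no single gene was called without the block (0 of 11614 by limma, 347 at an unadjusted p under 0.05, smallest adjusted p 0.999), while 3 lists of markers passed at a preset correlation. None of these 3 passed with an estimated correlation (adjusted p = 0.436 for adipocyte markers and 0.641 for macrophage and erythroid markers). The 13 adipocyte markers were all lower in NASH, with a median of -3.00, and Car3 (8.00-fold lower, log2 -3.00, SE 0.88, n = 3 per group), Plin1, a lipid droplet coat protein (-2.80, SE 1.06), Cidec (-2.01) and Fabp4 (-1.63) had the smallest p. The 19 macrophage and dendritic cell markers were all higher, with a median of 0.68, led by Fcer1g (1.09, SE 0.45), the complement component C1qb (0.92, SE 0.41), Cd74 (0.80) and H2-Ab1 (0.80). Haemoglobin and other erythroid genes were higher too, with a median of 1.16 and Alas2 at 1.44 (SE 0.47).

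The adipocyte list passed with a camera adjusted p of 8.5e-14. Adjusted over the list alone 10 of 13 were lower with the block, 0 without it. Control replicate 1 stood apart: the mean of the markers was at log2 9.97, 6.97 and 6.96 in control replicates 1 to 3 and 4.17, 6.33 and 4.97 in NASH, and within replicates 2 and 3 the median was -1.24 (8.6e-05). The macrophage list passed at 8.5e-09 (adjusted p = 0.641 with an estimated correlation; within replicates 2 and 3 median 1.01), with 0 members passing over the list alone. The erythroid list passed at 1.1e-05 (adjusted p = 0.641 with an estimated correlation), with 5 of 8 higher adjusted over the list alone with the block. Interferon-response genes were higher in 21 of 27, with a median of 0.47 (6.1e-05; adjusted p = 0.815 with an estimated correlation), Irf7 at 1.20, B2m at 0.82, Rtp4 at 1.45 and Ifit1 at 1.22. Oxidative phosphorylation was positive in 38 of 43 with a median of 0.12 (6.8e-05; adjusted p = 0.815 with an estimated correlation), but not within replicates 2 and 3 (0.0672), without control 24-week replicate 3 (0.18; with the block median 0.070, adjusted p = 0.071), with the block without NASH 24-week replicate 1 (median 0.079, adjusted p = 0.051) or with the block after the GC and length trend was removed (median 0.0057, adjusted p = 0.72). The interferon call with the block was lost without NASH 24-week replicate 3 (0.061).

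**Figure D4:**
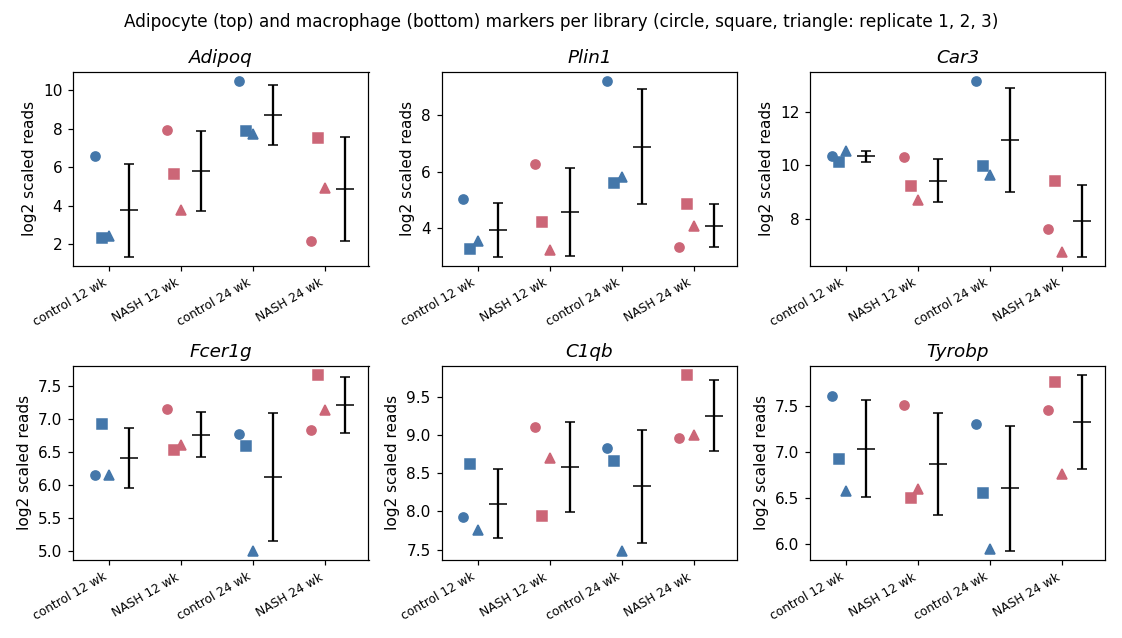
Log2 scaled reads of 3 adipocyte markers (Adipoq, Plin1, Car3) and 3 macrophage markers (Fcer1g, C1qb, Tyrobp) in each of the 12 libraries (points; circle, square and triangle are replicates 1, 2 and 3), by group, with the group mean ± SD of 3 libraries as bars. Adipoq is at 10.5 in control 24-week replicate 1 and at 2.17 in NASH 24-week replicate 1.

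Another 3 lists were lower at 24 weeks, each beside the lower adipocyte markers. Lipid droplet and uptake genes had a median of -0.30 (0.00273; adjusted p = 0.641 with an estimated correlation), with Cidec, Fabp4 and Plin4 (-2.12), 2 of which are also adipocyte markers here. The call was lost within replicates 2 and 3 (0.0552) and without NASH 24-week replicate 1 (0.20), and with the block without control 24-week replicate 1 (median -0.12, adjusted p = 0.096). Genes with a mean of at least log2 of 100 alone ended it too (0.066), as they did the next list's call (0.066). Fatty acid and triglyceride synthesis had -0.24 (0.0383; adjusted p = 0.770 with an estimated correlation), with Acly (-0.72), Gpam (-0.73) and Fasn (-1.09), and was lost with the block (0.0553), under median-of-ratios scaling (0.071), within replicates 2 and 3 (median -0.0015, 0.839) and without replicate 1 of control (0.67) or NASH (0.35). Immediate early and heat shock genes had -0.23 (0.0219; adjusted p = 0.699 with an estimated correlation), with the chaperone Hsp90aa1 at -0.48 and Jun at -0.53, and were lost with the block (0.0778), within replicates 2 and 3 (0.841), without control replicate 2 (0.33) and without NASH replicate 1 (0.85). Male-biased kidney genes passed with the block alone (median -0.58, 3.2e-04, without it 0.469; adjusted p = 0.414 with the block and an estimated correlation), with Odc1 at -0.65 and Cyp4a12a at -1.41. In the absence of NASH 24-week replicate 1 the median was 0.98 without the block, and with it the list stayed lower.

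With the block, limma called 1 gene at 24 weeks: Azgp1, a zinc-binding glycoprotein linked to lipid mobilisation, fell 2.70-fold (-1.43, block SE 0.11, adjusted p = 9.4e-04), with 1124 genes at an unadjusted p under 0.05. It changed by -1.41 within replicates 2 and 3 (adjusted p = 0.0010) and by -1.52 at 12 weeks. Azgp1 (gene ID 12007) lies on mm10 chromosome 5 from 137981521 to 137990232. The genes with the smallest p without the block, none passing, were Mogat2, an enzyme of triglyceride synthesis (1.18, 2.27-fold, SE 0.23), Slc51b (0.69), Sorbs3 (0.59), Rida (0.53) and Ebp (0.50) on the higher side, and Klf10 (-0.96), Tuba4a (-0.70), Gpd2 (-0.60), Slc37a4 (-0.53) and Hsp90aa1 on the lower. With the block Rdh16f2 (1.89), Apoe (1.14), Gsto1 (0.79), Acly, Gsta3 (-0.66) and Nudt12 (-0.60) came next, with adjusted p from 0.188 to 0.259. Weights for sample quality gave 80 genes, replicates 2 and 3 alone gave 12, and the block without NASH 24-week replicate 1 gave 4, without control 12-week replicate 1 gave 3 and without control 12-week replicate 2 or NASH 12-week replicate 1 gave 2.

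Fibrosis genes at 24 weeks had a median of 0.15 (camera adjusted p = 0.849), with Col1a1 at 0.72 (SE 0.39), Fn1 at 0.51, Acta2 at -0.34 and Postn at -1.10. Within replicates 2 and 3 the list passed upwards at 0.45 (0.0048), without control 24-week replicate 1 upwards at 0.52 (0.0252), and without control 24-week replicate 3 downwards at -0.15 (0.0232), so single libraries set its direction. Tubular injury genes had 0.24 (0.469), with Havcr1 at -0.32 and Vcam1 at 0.87. Hepatocyte markers had 0.56 (0.0992), clock genes -0.15 (0.434), bile acid handling 0.27 (0.239), cholesterol synthesis -0.086 (0.671), fatty acid oxidation -0.094 (0.349), the tricarboxylic acid cycle 0.044 (0.624), NRF2 targets 0.11 (0.849, test pointing down), the unfolded protein response 0.053 (0.604), cytokines 0.077 (0.469) and complement 0.0018 (0.849, mean below 0). Gluconeogenesis and glycolysis had 0.023 (0.913, mean and test below 0), podocytes 0.11 (0.624), proximal tubule 0.0084 (0.624, mean and test below 0), the distal nephron 0.14 (0.913, mean and test below 0), collecting duct -0.026 (0.849, mean above 0), endothelium 0.18 (0.486), the juxtaglomerular list 0.040 (0.404), female-biased genes 0.77 (0.469), cell cycle 0.10 (0.434), cytochrome P450 -0.12 (0.469), retinoid genes -0.054 (0.624) and amino acid metabolism 0.10 (0.589). Plin2 was at -0.14, Cpt1a at -0.36 and Slc34a1 at 0.022.

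The effects at both times were then set against each other. Called genes at 12 and 24 weeks shared 0 genes without the block and 1, Azgp1, with it (0.0985 by independence, Fisher's exact p = 0.0985). Quality weights gave 22 and replicates 2 and 3 alone 6. Across all genes the changes correlated at r = 0.28, and 63.1% had the same sign. Genes are not independent replicates. Of the 1494 genes called with the block at 12 weeks, 1188 (79.5%) had the same sign at 24 weeks, with a median absolute change of 0.58 at 12 weeks and 0.17 at 24 weeks. Their choice by the 12-week change makes the 12-week value larger. Over all genes these medians were 0.24 and 0.14.

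The difference of the NASH effect between 24 and 12 weeks asks which genes responded differently early and late. Among the genes with the smallest p were clock genes: Dbp had -5.68 (SE 1.10, 3 libraries per group), Npas2 2.58 (SE 0.40) and Nr1d2 -1.48, beside Ypel2 (2.15), Slc16a1 (1.41), Ndrg1 (1.29), Zfp697 (1.26), Slc2a5 (-1.72), Gjb2 (-1.10) and Gpd2 (-0.98). None passed (0 called by limma, 425 at an unadjusted p under 0.05, smallest adjusted p 0.565). With the block 1 gene was called, Nfil3, a repressor that opposes Dbp in the clock (3.24, block SE 0.37, adjusted p = 0.0340), which lies outside the naming rule and was named after its values were seen. Nfil3 (gene ID 18030) lies on mm10 chromosome 13 from 52967209 to 52981039. The next block values, Npas2, Ypel2, Dbp, Gpd2, Itga6 (1.60), Prom1 (1.49) and Nav2 (1.47) at an adjusted p of 0.0739, and G0s2 (-1.96), Tef (-1.32) and Nudt19 (-1.30), did not pass. Replicates 2 and 3 alone gave 73 calls (50 higher, 23 lower), among them Npas2 (3.05) and Dbp (-6.04), and the block gave 29 without control 24-week replicate 1, 11 without control 12-week replicate 1, 10 without NASH 24-week replicate 1, 8 without NASH 12-week replicate 1, and 0 without replicates 2 or 3 of either control group, NASH 12-week replicate 3 or NASH 24-week replicate 3.

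As lists, the NASH effect was lower at 24 than at 12 weeks for adipocyte markers (median -3.70, all 13 negative, camera adjusted p = 3.2e-15; adjusted p = 0.153 with an estimated correlation), and beside them for oxidative phosphorylation (-0.18, 39 of 43 negative, 7.3e-10, 0.642 with an estimated correlation), lipid droplet genes (-0.45, 5.0e-05, 0.153), immediate early genes (-0.22, 2.0e-04, 0.284) and the clock (-0.80, 2.9e-04, 0.0783). Adjusted over the list alone, 3 clock genes were higher and 9 lower. With the block and the GC and length trend removed, the median was -0.0042 for oxidative phosphorylation (adjusted p = 0.0366) and -0.023 for gluconeogenesis and glycolysis (0.0468). Gluconeogenesis and glycolysis (-0.12, 0.00673, 0.642 with an estimated correlation), the unfolded protein response (-0.13, 0.0203, 0.777) and fatty acid synthesis (-0.26, 0.0249, 0.688) also passed. Within replicates 2 and 3 the unfolded protein response (adjusted p = 0.0690) and fatty acid synthesis (median 0.25, adjusted p = 0.812) did not, and the immediate early median was -0.016 (adjusted p = 0.00765). With the block the immediate early call was lost without NASH 24-week replicate 1 (-0.12, adjusted p = 0.14). Both were lost without control 12-week replicate 2 (0.15 and 0.085), control 24-week replicate 1 (0.25 and 0.36) or NASH 24-week replicate 1 (0.37 and 0.088). The unfolded protein response was lost without control 12-week replicate 3 (0.16), and fatty acid synthesis without NASH 12-week replicate 2 (0.055). Quantile normalization ended the calls of fatty acid synthesis (0.090), gluconeogenesis and glycolysis (0.15) and the unfolded protein response (0.079), and median-of-ratios scaling that of fatty acid synthesis (0.11). The block's calls of these 3 were lost under quantile normalization too (0.11, 0.19 and 0.14), and that of fatty acid synthesis under median-of-ratios scaling (0.076). The block's call of fatty acid synthesis was lost without replicate 1 of the 12-week controls (median -0.055, adjusted p = 0.10), of the 24-week controls (0.13, 0.48) or of NASH at 24 weeks (-0.18, 0.14), or NASH 12-week replicate 2 (0.093). Its call of the unfolded protein response was lost without control 12-week replicates 2 (-0.077, 0.21) or 3 (-0.067, 0.15), control 24-week replicate 1 (-0.046, 0.21), NASH 12-week replicates 2 (0.065) or 3 (0.057) or NASH 24-week replicate 1 (-0.014, 0.88). The block added fatty acid oxidation (-0.12, 0.0264, 0.884 with an estimated correlation), podocyte markers (0.34, 0.0264, 0.678) and male-biased genes (-0.81, 2.7e-04, 0.217). Fatty acid oxidation lost its call with median-of-ratios scaling (0.095), quantile normalization (0.34) or without control 12-week replicates 2 (0.16) or 3 (0.60), control 24-week replicates 2 (0.31) or 3 (0.21), NASH 12-week replicate 1 (median 0.068, adjusted p = 0.87) or NASH 24-week replicate 1 (median 0.17, adjusted p = 0.98). Podocyte markers lost theirs after the GC and length trend was removed (0.23) and without control 12-week replicate 2 (0.15), control 24-week replicate 2 (0.052), NASH 12-week replicate 3 (0.16) or NASH 24-week replicates 1 (0.065) or 3 (0.16). Male-biased genes lost theirs with quantile normalization (0.060), and in the absence of NASH 24-week replicate 1 their median was 0.82 without the block and stayed negative with it. Without control 24-week replicate 1 the medians of the unfolded protein response (0.021) and fatty acid synthesis (0.19) turned positive. Fatty acid synthesis was lost with a mean of at least log2 of 100 (0.054).

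In control mice, 24 weeks against 12 weeks showed the list of fat use genes higher at a preset correlation. With an estimated correlation its adjusted p was 0.0881, that of adipocyte markers 0.0881 and that of cholesterol synthesis 0.235, and with fry 0.102 for each. The 30 genes of fatty acid oxidation and PPARA targets had a median of 0.76 with 29 positive, led by Pdk4, which turns pyruvate away from oxidation (11.4-fold, log2 3.51, SE 0.77, n = 3 per group), Ucp2 (1.31) and Acadvl (0.64). Cholesterol synthesis was lower in 23 of 24 genes (median -0.65), with Msmo1 (-1.57), Idi1 (-1.45) and Insig1 (-1.04). Adipocyte markers were higher in 13 of 13 (median 2.95), with Lipe at 2.39 and Adipoq at 4.93 (SE 1.57).

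No gene passed without the block (0 by limma, 910 at an unadjusted p under 0.05, smallest adjusted p 0.323): Pnpla2 (1.08), Klf10 (1.53), Gpd2 (0.79), Slc27a1 (1.30), Slc2a5 (1.40), Il13ra1 (-0.71), Apbb2 (-0.75), Ccser2 (-0.80), Veph1 (-1.09) and Hsd3b2 (-1.52) had the smallest p. With the block 20 were called, 4 higher and 16 lower. Those higher were Plin4, a droplet coat protein (15.6-fold, 3.97, block SE 0.60, adjusted p = 0.0466), G0s2, an inhibitor of the lipase Pnpla2 (2.01, 0.0321), Pnpla2 itself (0.0466) and Gpd2 (0.0321), and those lower were led by Hsd3b2, Veph1, Tmem64 (-0.999), Gnpda1 (-0.93) and Dleu7 (-0.75). Within replicates 2 and 3 there were 755 calls (271 higher, 484 lower), Xist as a covariate 3, and the block 434 without control 24-week replicate 1, 90 without NASH 12-week replicate 1, 68 without control 12-week replicate 1, 37 without NASH 24-week replicate 1, 3 or fewer without NASH 12-week replicate 3 or NASH 24-week replicates 2 or 3, and 0 without control replicates 2 or 3 of either time. With the block and median-of-ratios scaling 4 were called, 2 each way, and 5 after the GC and length trend was removed.

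The fatty acid oxidation list passed at a camera adjusted p of 5.0e-20, with 2 members higher adjusted over the list alone and 20 with the block. The adipocyte list passed at 6.0e-14 (9 higher adjusted over the list alone), immediate early genes at 8.8e-07 (median 0.62; Junb 1.75, Jun 1.08; 3 higher adjusted over the list alone), lipid droplet genes at 3.5e-06 (median 0.34, 7 higher), NRF2 targets at 0.0148 (median 0.064, 0 higher) and the clock at 0.0127 (median 0.46, 4 higher and 1 lower). Each of these had an adjusted p = 0.0881 with an estimated correlation. Cholesterol synthesis passed at 2.3e-08 (adjusted p = 0.235 with an estimated correlation; 13 lower adjusted over the list alone with the block) and gluconeogenesis and glycolysis at 1.7e-05 (median 0.21, Pck1 2.13; adjusted p = 0.139 with an estimated correlation). Oxidative phosphorylation (0.017, 0.0148, adjusted p = 0.936 with an estimated correlation), fatty acid synthesis (0.32, 0.0294, 0.685) and complement (0.19, 0.0370, 0.716; with the block 0.0700) passed more narrowly. Quantile normalization ended the calls of NRF2 targets (0.15), the clock (0.13), oxidative phosphorylation (0.41), fatty acid synthesis (0.13) and complement (0.13), and median-of-ratios scaling those of fatty acid synthesis (0.16), complement (0.11) and the clock (0.11). Without control 12-week replicate 1 oxidative phosphorylation (0.15) and NRF2 targets (0.082) were lost. Without control 12-week replicate 2 fatty acid synthesis (0.073), complement (0.060) and the clock (0.050) were lost, and complement without control 12-week replicate 3 (0.18). Without control 24-week replicate 1 fatty acid synthesis (median -0.14, 0.61) and complement (median -0.0053, 0.28) were lost, and without replicate 2 oxidative phosphorylation (median -0.048, 0.96), NRF2 targets (0.26) and complement (0.22). The block added tubular injury (0.0376, 0.683 with an estimated correlation), hepatocyte markers (0.0376, 0.510) and cytochrome P450 genes (0.0216, 0.240). These 3 were lost with median-of-ratios scaling (0.13, 0.13 and 0.059) and quantile normalization (0.19, 0.23 and 0.28), hepatocyte markers and cytochrome P450 genes without control 12-week replicate 2 (0.13 and 0.14), and hepatocyte markers without control 24-week replicate 2 (median -0.18, adjusted p = 0.55). With the block and the GC and length trend removed, oxidative phosphorylation (median -0.052, adjusted p = 0.85) and NRF2 targets (0.034, 0.0642) were lost. The medians of gluconeogenesis and glycolysis (0.076, adjusted p = 0.00163), complement (0.064, 0.0624), hepatocyte markers (0.11, 0.0268) and tubular injury (-0.042, 0.0474) were then lower than before, and that of cytochrome P450 genes was higher (0.13, 0.00564). Tubular injury was lost without control 12-week replicate 3 (median -0.078, adjusted p = 0.26) and control 24-week replicates 1 (-0.12, 0.15) or 2 (-0.052, 0.32). The block's calls were lost under quantile normalization for NRF2 targets (0.21), the clock (0.17), oxidative phosphorylation (0.39) and fatty acid synthesis (0.13), and under median-of-ratios scaling for the clock (0.13) and fatty acid synthesis (0.099). They were lost without control 12-week replicate 2 for NRF2 targets (median 0.13, adjusted p = 0.053) and the clock (0.34, 0.18), without control 24-week replicate 1 for the clock (0.064) and fatty acid synthesis (0.039, 0.66), and without control 12-week replicate 1 for the latter (0.11, 0.070). Without control 24-week replicate 2 the block lost NRF2 targets (-0.0083, 0.18) and oxidative phosphorylation (-0.029, 0.31). Within replicates 2 and 3 fatty acid synthesis had a median of -0.039 (0.692), oxidative phosphorylation -0.024 (0.0672), tubular injury -0.095 (0.0294) and complement -0.072 (0.0358).

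In NASH mice fatty acid oxidation was again higher and cholesterol synthesis again lower at 24 than at 12 weeks at a preset correlation, but not with an estimated one (adjusted p = 0.465 for both). The same 12-week NASH libraries enter this contrast and the 12-week one, so their results are not independent. Fatty acid oxidation was positive in 29 of 30 genes with a median of 0.59, Pdk4 at 2.68 (6.40-fold, SE 0.77, n = 3 per group), Acot1 at 2.21, Acot2 at 1.68 and Cyp4a10 at 2.34. Cholesterol synthesis was negative in 23 of 24 with a median of -0.48, and Insig1 was at -0.93. Oxidative phosphorylation was negative in 40 of 43 (median -0.12), and macrophage markers positive in 18 of 19 (median 0.47), with Cd68 at 1.40. Neither passed with an estimated correlation (adjusted p = 0.975 for both), and with the block and the GC and length trend removed the oxidative phosphorylation median was -0.074 (adjusted p = 0.00707).

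These 4 lists passed with camera adjusted p of 3.5e-14, 1.3e-09, 3.9e-07 and 1.2e-04. Over the list alone 0 members passed in each, and with the block 18 fatty acid oxidation genes were higher and 4 cholesterol genes lower. With the block the macrophage call was lost without NASH 12-week replicate 2 (median 0.093, adjusted p = 0.43) or NASH 24-week replicate 2 (median 0.27, adjusted p = 0.051), and within replicates 2 and 3 the median was 0.83 (adjusted p = 2.2e-05). Male-biased genes passed with the block alone (-0.74, 5.0e-04, Odc1 -1.58; adjusted p = 0.419 with the block and an estimated correlation). In the absence of NASH 24-week replicate 1 their median was 0.87 without the block, and with it they stayed lower. No gene passed without the block (0 by limma, 553 at an unadjusted p under 0.05): Slc16a1 (1.61, SE 0.20) and Ndrg1 (1.42, SE 0.19) had an adjusted p of 0.0706, ahead of Slc25a30 (1.11), Ypel2 (1.45), Nectin1 (0.91), Keg1 (-1.26), Gjb2 (-0.84), Nat8f1 (-1.02), Nmrk1 (-1.08) and Coq10b (-0.87). With the block Slc16a1, Ndrg1 and Nfil3 (2.30) rose, each at an adjusted p of 0.0308. Nfil3 was again named after its values were seen. Slc16a1 and Ndrg1 lost their calls with median-of-ratios scaling (0.070 for both) and Slc16a1 with the GC and length trend removed (change 1.63, adjusted p = 0.051). Clpx (0.86), Ak4 (-0.96) and Nat8f6 (-0.73) came next with the block and did not pass. Replicates 2 and 3 alone gave 541 calls (292 higher, 249 lower), and the block gave 170 without NASH 12-week replicate 1, 141 without NASH 24-week replicate 1, 11 without control 12-week replicate 1, 1 without NASH 24-week replicate 2, and 0 without control 12-week replicate 3, control 24-week replicates 2 or 3, NASH 12-week replicates 2 or 3 or NASH 24-week replicate 3.

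Averaged over both times, these were among the genes with the smallest p, and none of them passed without the block. Slc16a1 was 2.30-fold lower (-1.20, SE 0.14, 6 libraries per side), the glutathione transferase Gsta3 lower (-0.96), Npas2 (-1.32) and Ndrg1 (-0.78) lower, and Mogat2 2.25-fold higher (1.17, SE 0.16), with Sorbs3 (0.69), Ebp (0.58), Coq10b (0.68) and Dbp (2.64) also on the higher side. Without the block none passed (0 by limma, 1579 at an unadjusted p under 0.05, smallest adjusted p 0.0521). The fits under quantile normalization called 5, and under median-of-ratios scaling 1. With the block 1207 were called, 352 higher and 855 lower, but 628 higher and 615 lower with median-of-ratios scaling and 534 higher and 627 lower with quantile normalization. The genes with the largest changes among the block's calls above the median level, named after the data were seen, were not held to the rule's condition that libraries do not overlap: NASH and control overlap, for instance, for Dbp and Npas2 at 24 weeks, for Car3 at 12 weeks and for Azgp1 at both times. Those higher were Dbp, Ttr (2.06), Slc38a3 (1.82), Ugt2b37 (1.69), Rarres2 (1.46), Slc5a10 (1.45), Napsa (1.33), the haemoglobins Hba-a2 (1.30) and Hba-a1 (1.29), the sterol enzyme Cyp51 (1.28), Mogat2 (block adjusted p = 0.00126) and Agt, the angiotensin precursor (1.16). Those lower were Car3 (-1.95), Azgp1 (-1.47, block adjusted p = 2.0e-05), Npas2, Lmbrd2 (-1.27), Cyp2a5 (-1.26), Slc16a1, Cyp4a12a (-1.14), Ppard (-1.11), C1galt1 (-1.05), Itgb8 (-1.03), Calb1 (-1.01) and Snx29 (-1.001). Replicates 2 and 3 alone gave 123 calls (51 higher, 72 lower), and the block 210 without control 24-week replicate 3, 265 without control 12-week replicate 3, 364 and 389 without NASH 24-week replicates 3 and 1, 437 without control 24-week replicate 1, 467 without NASH 12-week replicate 1, 625 without control 12-week replicate 1 or 2 and 759 without NASH 12-week replicate 2. Single leave-outs or the GC and length trend's removal (377 calls) ended the calls of Napsa, Agt, Car3, Cyp4a12a, Ppard, Cyp51, Hba-a1, Hba-a2, Rarres2, Slc38a3, Ugt2b37, Cyp2a5, Calb1 and Ttr, with adjusted p up to 0.11. With the trend removed the changes were 1.23 for Rarres2, 1.18 for Napsa, 1.04 for Agt, -2.02 for Car3 and -1.13 for Cyp4a12a.

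As lists, the average effect was higher for oxidative phosphorylation (median 0.22, 39 of 43 positive, camera adjusted p = 4.6e-15; 15 higher adjusted over the list alone), interferon response (0.33, 9.9e-06; 1 higher over the list alone, 4 over all genes with the block), macrophage markers (0.44, 9.8e-05), erythroid genes (0.96, 1.2e-04; 5 higher adjusted over the list alone), the unfolded protein response (0.16, 0.0246) and hepatocyte markers (0.48, 0.0262; with the block 0.0873). Each had an adjusted p = 0.806 with an estimated correlation. With the block and the GC and length trend removed, the oxidative phosphorylation median was 0.020 and its call was lost (adjusted p = 0.062). The unfolded protein response was lost under quantile normalization (0.075) and without control 12-week replicates 2 or 3, control 24-week replicate 2 or NASH 24-week replicates 2 or 3 (0.079 to 0.14). The block's call of it was lost under quantile normalization (0.13) and median-of-ratios scaling (0.074), and without replicates 2 or 3 of any group (0.062 to 0.16). Hepatocyte markers were lost under both scalings (0.056 and 0.071) and without control 12-week replicate 2, control 24-week replicate 3 or replicate 1 of either NASH group (0.062 to 0.14), and with a mean of at least log2 of 100 (0.36). Across the 6 contrasts, no list called with the preset correlation held with an estimated one.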

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

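The test on time of day, the splits that part all same-numbered pairs at both times, the fit of replicates 2 and 3 alone and the fits that combine the block with another change were chosen only after the result was seen.

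For 8 gene lists and 1 gene the NASH effect differed between 24 and 12 weeks by a test of the difference itself. The differences of the list medians were -3.70 for adipocyte markers (camera adjusted p = 3.2e-15), -0.80 for the clock (2.9e-04), -0.45 for lipid droplet and lipid uptake (5.0e-05), -0.22 for immediate early and heat shock genes (2.0e-04) and -0.18 for oxidative phosphorylation (7.3e-10). They were -0.26 for fatty acid and triglyceride synthesis (0.0249), -0.13 for the unfolded protein response (0.0203) and -0.12 for gluconeogenesis and glycolysis (0.00673). With the block and the GC and length trend removed, the oxidative phosphorylation median was -0.0042 (adjusted p = 0.0366) and that of gluconeogenesis and glycolysis -0.023 (0.0468). The immediate early median was -0.016 within replicates 2 and 3 (adjusted p = 0.00765), and with the block that list was lost without NASH 24-week replicate 1 (-0.12, adjusted p = 0.14). With an estimated correlation none of the 8 passed (0.0783 for the clock to 0.777 for the unfolded protein response). Without control 24-week replicate 1 the medians of fatty acid synthesis (0.19, adjusted p = 0.36) and the unfolded protein response (0.021, adjusted p = 0.25) turned. Both were also lost without control 12-week replicate 2 (0.085 and 0.15) and NASH 24-week replicate 1 (0.088 and 0.37), the unfolded protein response without control 12-week replicate 3 (0.16), and fatty acid synthesis without NASH 12-week replicate 2 (0.055). The gene was Nfil3, at 3.24 with the block (adjusted p = 0.0340). The block called 0 genes in this contrast, Nfil3 included, without replicates 2 or 3 of either control group, NASH 12-week replicate 3 or NASH 24-week replicate 3.

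The first pattern weighed is that clock genes and many other genes differed between NASH and control at 12 weeks, and no table argues against either technical explanation tested. If the clock phase of the libraries carried the other calls, their slopes on the clock index within groups would follow their changes. They did for 66.1% of 1482 non-clock genes (45.1% to 79.2% without 1 library), against 55.3% of all genes, and this stays open. Time of day at dissection, not in the labels, also stays open: the clock index differed by 3.62 at 12 weeks. Its range in the 24-week controls was 0.375 of that, less than the test asked for. Controls shifted: -1.12 to -0.63 at 12 weeks, 0.025 (replicate 1) to 1.38 at 24 weeks. An effect of NASH, diet or CCl4 on the clock stays open as untested.

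The second pattern is that 76.6% of the 1494 genes called with the block at 12 weeks were lower in NASH (71.0% to 84.5% without 1 library). With the GC and length trend removed 82.7% of the calls were lower (78.0% to 85.5%), though the calls fell to 519. That removal keeps the mean of each library, and the median change of all genes was -0.078 after it and -0.080 before. It therefore cannot decide on GC content and length as a cause, which stays open. The tables argue against depth acting only through weakly expressed genes, since 73.4% of 1032 called genes above the median level were lower (68.9% to 82.1%). That subset keeps the shift of the median, so it cannot decide on depth as a cause of the shift. The tables argue against the 100 most abundant genes as the only cause. With totals taken outside them 71.0% were lower (68.6% to 78.9%), and the median change was still -0.060. Scaling as such stays open: median-of-ratios scaling gave 50.3% lower, but it sets the median change to about 0 and so fixes that outcome. An effect of NASH, diet or CCl4 on many transcripts stays open as untested.

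The third pattern is that adipocyte markers were lower in NASH at 24 weeks, and the tables argue against neither explanation tested. Fat tissue carried along in some libraries may have set the levels: the spread of a marker about the others was 0.663 of its own (0.602 to 0.692 without 1 library), and control replicate 1 held Adipoq at 10.5 and Cfd at 13.0. If lipid stored in kidney cells set the list, Adipoq, which fat cells secrete, would fall by less than 0.5 of the list's median (-3.00). It fell further than that (-3.82, block SE 1.41), but 1 gene cannot decide for the list, so this stays open too. Within replicates 2 and 3 the median was -1.24, and Cidec, Fabp4, Lipe and Cidea also stand in the lipid droplet list. A loss of fat cells or of their transcripts in NASH stays open as untested.

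Other splits of the same libraries were counted for each contrast. For the 4 contrasts of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. At 12 weeks the real split called 6 genes and the highest other 0, and with the block 1494 and 0, each reached by 1 split of 10. At 24 weeks the values were 0 and 0, reached by 10 splits, and with the block 1 and 0. For time in controls they were 0 and 0 (10 splits), and with the block 20 and 0. For time in NASH they were 0 and 0 (10 splits), and with the block 3 and 0. Of the 10 splits 4 part as many same-numbered pairs as the real one, and the others of these called 0 genes in every one of these contrasts. For the difference between times, 100 splits within each time were drawn, and 100 gave as many calls as the real 0, with a highest other of 4. With the block 10 gave as many as the real 1, and the highest other was 1207, because swapping the labels at 1 time turns this contrast into the average effect; chance is not excluded for either count. For the average effect 100 of 100 gave as many as the real 0, with a highest other of 3, so chance is not excluded there. With the block 1 of 100, the real one, gave 1207, and the highest other gave 949. Of all 32 splits that part 3 same-numbered pairs at each time, as the real one does, 1, the real one, gave 1207, a share of 0.031. That is the smallest share that 32 splits can give, and these splits were chosen after the result was seen. Every one of them with more than 1 call kept the real 12-week groups. The count therefore rests on the 12-week grouping, and chance is not excluded for it. The split with 949 calls keeps the real 12-week groups and mixes those at 24 weeks, and the highest of the 18 splits with the real groups at neither time, mirrored or not, gave 0.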

How the results depend on the processing

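The fits of replicates 2 and 3 alone, the block combined with a scaling, a filter, a left-out library or a removed GC and length trend, the filter at log2 of 100 and the covariates for Xist with the clock index were chosen only after the data were seen. Where a value changed and no reason is given, the cause was not tested. Results compared are 283 gene values and 59 lists across the 6 contrasts, beside the counts of calls.

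Pseudocounts of 0.1 and 5 and no filter kept all 283 gene values and 59 lists on their side of the threshold and in their direction. A mean of at least 5 kept the 280 gene values it measured and 57 lists, and ended the calls of 2. No trend kept 281 gene values and ended 2 calls. Quantile normalization kept 277 gene values, added 4 calls and ended 2, and kept 44 lists and ended 15. The average effect then had 5 calls (1 higher, 4 lower), and 4 lists were called at 12 weeks. Median-of-ratios scaling kept 278 gene values, added 2 calls and ended 3, kept 50 lists and ended 9, and gave 1 call for the average effect. The filter at log2 of 100 kept 252 gene values and added 1 call, kept 53 lists and ended 6 list calls, and also gave 1 call for the average effect. The compared groups alone gave 1 call at 12 weeks and 1 for time in controls, where fewer libraries inform the spread. The estimated correlation and fry each left 0 lists at 12 and 24 weeks and ended all 46 list calls made without the block; the other 13 lists were not called with or without these changes.

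The replicate block added 74 calls among the gene values and kept 209, and for lists kept 45, added 9 and ended 5. It called 1494 genes at 12 weeks (350 higher, 1144 lower), 1 at 24 weeks, 1 for the difference, 20 for time in controls, 3 for time in NASH and 1207 for the average effect, with 1 gene shared by both times. With median-of-ratios scaling the counts were 1379 (686 higher, 693 lower), 1, 1, 4, 1 and 1243 (628 higher, 615 lower), 1 shared, and 5 lists at 12 weeks. With quantile normalization they were 1230 (532 higher, 698 lower), 1, 4, 32, 4 and 1161, 1 shared, and 2 lists. With the filter at log2 of 100 they were 1540, 1, 1, 19, 3 and 1207, 1 shared. With the GC and length trend removed they were 519 (90 higher, 429 lower), 1, 1, 5, 2 and 377, 1 shared, and Vldlr at 12 weeks turned to 0.020. The oxidative phosphorylation median then moved from 0.31 to 0.0073 at 12 weeks, from 0.12 to 0.0057 at 24 weeks, from -0.18 to -0.0042 for the difference, from 0.22 to 0.020 for the average, from 0.017 to -0.052 for time in controls and from -0.12 to -0.074 for time in NASH.

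Sample quality weights called 1176, 80, 40, 1018, 1131 and 1692 genes in the same order of contrasts, 22 shared, and turned Xist (0.059) at 12 weeks and Acta2 (0.55) at 24 weeks. The Xist covariate called 753 at 12 weeks, 3 for time in controls, 4 for time in NASH and 593 for the average effect, and added 60 calls among the gene values. The fit of replicates 2 and 3 alone called 385, 12, 73, 755, 541 and 123 genes, 6 shared, and 14 lists at 12 weeks. They turned Col1a1 (-0.091) and Fn1 (-0.023) at 12 weeks, Acta2 (0.12) and Xist (-0.024) at 24 weeks, and the test of fatty acid synthesis at 24 weeks (median -0.0015).

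Covariates for Xist and the clock index overlap with the NASH contrast at 12 weeks, since the index itself differs between those groups (3.62); they called 1 gene each at 12 weeks, for the difference, for time in NASH and for the average. Of the gene values 30 turned and of the lists 18. At 12 weeks these were Dbp (-0.84), Coq10b (-0.060), Pck1 (-2.42), Nr1d1 (-0.91), Ppard (1.51), Ypel2 (0.079), Col1a1 (-0.16), Acta2 (-1.67), Havcr1 (-2.32), Plin2 (-1.38), Tagln (-1.30), Dcdc2a (0.57), Krt20 (-0.84), Fh1 (-0.043), Xbp1 (-0.38), Ddit3 (-0.36), Cfd (-9.57), Lipe (-0.56), Adipoq (-8.38) and Fabp4 (-0.56). For the difference they were Dbp (0.92) and G0s2 (0.54), for time in controls Dcdc2a (0.19), Srebf1 (0.077), Cfd (-0.38), Dbp (-0.27) and Cyp24a1 (-1.27), and for the average Dbp (-0.38), Ugt2b37 (-0.11) and Ppard (0.56). List medians at 12 weeks were -0.24 for fibrosis and for tubular injury, -0.019 for the tricarboxylic acid cycle, -0.011 for gluconeogenesis, -0.36 for the unfolded protein response, -1.26 for adipocyte markers and -0.17 for the clock. For the difference they were 1.26 for fatty acid oxidation, 0.060 for gluconeogenesis, 0.46 for the unfolded protein response, -0.22 for podocytes, 0.011 for the clock and 0.14 for immediate early genes. Complement in controls over time had -0.20 and the average unfolded protein response -0.13. For adipocyte markers (-0.70) and male-biased genes (-0.19) in the difference and macrophage markers in the average (0.055) the test turned and the median did not.

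Leaving out each library, with or without the block, gave 0 to 1533 calls at 12 weeks, 0 to 4 at 24 weeks, 0 to 29 for the difference, 0 to 434 for time in controls, 0 to 170 for time in NASH and 0 to 1093 for the average, 0 to 3 shared, and 2 to 11 lists at 12 weeks and 7 to 15 at 24 weeks. A group left with 2 libraries takes its spread from limma's pool over all groups. Single values that turned ranged at 12 weeks from -0.11 to 0.84 for Acta2, -0.16 to 0.83 for Fn1, -0.56 to 1.46 for Havcr1, -0.028 to 0.52 for Plin2, -0.27 to 0.021 for Slc34a1 and -2.93 to 1.88 for Xist. At 24 weeks they ranged from -1.36 to 0.066 for Acaca, -3.21 to 0.15 for Acsm3, -3.84 to 0.79 for Cyp4a12a, -1.82 to 0.56 for Cyp4a12b, -1.37 to 0.46 for Havcr1, -0.65 to 0.34 for Plin2, -0.067 to 0.11 for Slc34a1 and -2.22 to 2.32 for Xist. Over time Acsm3 ranged from -3.90 to 0.20 in NASH and Apoa1 from -0.095 to 1.66 in controls. List medians at 24 weeks ranged from -0.15 to 0.52 for fibrosis, -0.14 to 0.59 for tubular injury, -1.76 to 0.98 for male-biased genes and -0.41 to -0.099 for immediate early genes, whose test turned. Male-biased genes ranged from -2.43 to 0.82 in the difference and -2.44 to 0.87 for time in NASH, and in the difference fatty acid oxidation from -0.39 to 0.17 and podocytes from -0.011 to 0.70.

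Count models were not run. The highest of several entries per gene has no value, because no 2 genes share a gene ID, and Xist has no value of its own with an Xist covariate. Depth was lowest in NASH 12-week replicates 2 and 3. Every deposited gene reaches 100 scaled reads in a library, so weaker transcripts are not seen at any setting.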

Other observations

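The labels give as many males as females in each group. By Xist and Ddx3y 1 of 3 libraries in each group reads as female. No hypothesis beyond those above was tested.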
